A study of Mus musculus with 4 samples.

How the data were processed

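Nuclei from flash-frozen kidneys of 3 male mice aged 12 weeks were pooled per group, per the labels, and each pool gave 1 RNA and 1 ATAC library with the 10x Genomics Multiome kit. ATAC-seq inserts adapters into open chromatin with a transposase, so the number of sequenced fragments over a region measures how accessible it is. The labels name 4 libraries, RNA and ATAC of wild-type control kidney and of kidney with a kidney-specific knockout of Glut2 (gene symbol Slc2a2). The fragment and peak data used here come from 1 library, the control ATAC library, which the identifier in the file headers matches to that library's name in the labels. The knockout libraries and the RNA of both groups were not analysed here. No genotype comparison was therefore made, and the comparisons are between cell classes within the control library.

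Fragments were produced with Cell Ranger ARC 2.0.2 on the mm10 (GRCm38) reference, per the file headers. Each line of the deposited fragments is 1 unique fragment of 1 barcode, with the count of read pairs that support it, per the file headers and the values. Duplicate read pairs were already collapsed into that count by the authors' software, and no scaling had been applied. The deposited peaks are coordinates, a start and an end in base pairs with no height or p-value, and were called by Cell Ranger ARC on this library alone, per the file headers. Seurat 5.1.0 and Signac 1.13.0 are named in the submitters' processing notes without their role. Whether fragment ends were shifted for the width of the transposase is not given in the sources used here. Gene positions came from the GENCODE M21 annotation of GRCm38, and all peaks on chromosomes lay within that build's chromosome lengths. Fragments on unplaced scaffolds were not used in comparisons. Coordinates are 1-based.

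A barcode was taken as a nucleus with at least 1000 and at most 50000 unique fragments in peaks and at least 20% of its fragments in peaks. Peak counts were weighted by TF-IDF with a scale of 10000, after leaving out peaks seen in fewer than 20 nuclei. They were reduced by truncated singular value decomposition to 31 components. The first component followed depth (Pearson r = 0.977 across nuclei) and was dropped. Nuclei with over 50% simulated doublets among their 40 nearest neighbours were removed. The remaining nuclei were clustered by the Leiden method at resolution 0.8 on a graph of 20 neighbours. Clusters were named from marker genes fixed before the data were examined. A name required at least 3 of its markers at a log2 ratio of at least 1 over other nuclei. Its mean marker ratio had to be at least 0.5 log2 units above that of the next name of another class. Among the 10 leading genes, markers of another class could not outnumber those of the named class. The proximal tubule and its S1, S2 and S3 segments counted as the same class here. No margin was therefore required between segments, and a cluster took the highest-scoring segment. After the data were examined, 2 demands were added: at least 10 fragments per marker, and at least 1 own marker among the 50 leading genes. These kept clusters 12 and 16 unnamed, with 95 nuclei (2.06%) and 38 nuclei (0.83%). Names come from chromatin alone, so classes are called "X-like", and clusters that shared a name were joined.

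Fragments were counted over each protein-coding gene and 2 kb upstream, summed over the nuclei of a class, and expressed as counts scaled to the in-peak fragments of that class (CPM). A gene inside another gene shares its fragments with it. Log2 ratios set a class against all other nuclei, with 0.5 added to each count, for 16682 genes with at least 200 fragments. Because the share of fragments in peaks differed between classes, the ratio of the median gene differed from 0, and ratios are given relative to that median. This scale was chosen after the data were examined. Rates carry exact Poisson intervals, ratios an interval from the exact binomial split of the fragments, and shares an exact Clopper-Pearson interval, all at 95%. With 1 library, these intervals cover counting error only, neither nuclei nor mice were treated as replicates, and no test was run.

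Before the data were examined, 20 gene lists with 400 distinct genes were fixed, and all list entries were found in the annotation. Markers of a class were left out of the lists for that class, while markers of other classes stayed in. A list's median ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean accessibility. A list is called high or low where it lies outside the central 95% of those random lists, a line chosen after the lists were fixed. The percentile describes this library and is not a p-value. Genes were named by a rule fixed beforehand for data without a labelled contrast. The rule takes Slc2a2 and, in each list, the 3 most and the 2 least accessible members in proximal tubule among those with at least 200 fragments. That rule was written for unlabelled libraries and was applied to the 1 labelled library because no second one was compared. Slc12a1, Tnf, Kap, Slco1a1, Egf and Foxi1 met the rule but were among the 10 leading genes of a cluster, so their values are not given as results.

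Consensus motifs were searched on both strands of 97826 peaks on the chromosomes. The mean log2 ratio of peaks with a motif was compared with that of peaks without it, matched on 10 bins each of GC content and mean accessibility. The same 24 motifs with their letters reversed served as controls. Some controls were found in few peaks, down to 10, and such controls can widen the range.

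The ratio and list calculations were tested on simulated counts for proximal tubule over other nuclei. Over the 16682 genes, 50 simulated at each of 4 fold changes were recovered with median log2 ratios of -2.00, -0.98, 1.01 and 2.02, against true values of -2, -1, 1 and 2. Intervals of 1000 unchanged genes held the true value in 95.7% of cases. Of 200 unchanged lists, 3.0% lay outside the central range, and all 20 lists with 12 of their 20 members doubled were called high. Unchanged genes in these simulations differed by counting error alone, whereas real gene ratios spread more widely. The share of such lists called high may therefore be lower in the real data. The motif calculation was tested on artificial peaks with random GC content and accessibility, not on peaks of this library. There, a simulated motif effect of 0.3 was recovered as 0.28 with matching and as 0.40 without it. Alternatives covered the depth and in-peak minimums, the minimum of fragments per gene, doublet removal, clustering resolution, promoters (1 kb each side of the start site) in place of gene windows, scaling, and the peaks and peak centres searched. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.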

Results

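Open chromatin was measured in single nuclei of wild-type mouse kidney, the control of a study of kidney-specific loss of Glut2. Glut2, encoded by Slc2a2, carries glucose out of proximal tubule cells towards the blood. The library, 1 pool of 3 male mice, held 129061700 unique fragments from 242201536 read pairs, or 1.88 read pairs per fragment. Of all fragments, 38.1% touched 1 of the 97882 peaks. There were 5246 barcodes that passed as nuclei, beside the 5723 nuclei estimated in the labels from both RNA and ATAC. After removal of 641 likely doublets (12.2%), 4605 nuclei remained. Nuclei that passed had a median of 15070 fragments and 6970 in peaks. The transcription start site enrichment was 21.2, taken over the 5723 barcodes with the most fragments in peaks, some of which did not pass. Over all barcodes, 71.5% of fragments were below nucleosome length. There are no replicates, and all intervals cover counting error only.

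Proximal tubule-like nuclei were the most numerous class, with 44.4% of the 4605 nuclei (95% interval 42.9 to 45.8%). The proximal tubule reabsorbs most filtered glucose, amino acids and phosphate. These nuclei fell into S1-like (17.5%), S2-like (19.7%) and S3-like (7.12%) clusters, named for the successive segments of the tubule. Endothelial-like nuclei made up 16.1%, thick ascending limb (TAL)-like 10.6%, distal convoluted tubule (DCT)-like 7.49%, mesenchymal-like 5.73%, principal-like 5.67%, intercalated-like 2.48% and macrophage-like 2.15%. A further 5.39% stayed unnamed. No cluster was named for the connecting tubule. Its markers were among the 10 leading genes of the DCT-like cluster (Calb1 and Slc8a1) and of the larger principal-like cluster (Trpv5). These 2 classes may therefore hold connecting tubule nuclei. Median in-peak depth ranged from 3916 fragments in macrophage-like to 9846 in proximal tubule-like nuclei, so the depth minimum bears on these shares.

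Slc2a2 (ENSMUSG00000027690.13, chromosome 3, 28697903 to 28731359, plus strand, GRCm38) was accessible mainly in the proximal tubule. Proximal tubule-like nuclei had 3843 fragments over it, or 199.4 counts scaled to in-peak fragments (CPM, 193.1 to 205.8), against 277 fragments and 21.4 CPM (19.0 to 24.1) in all other nuclei. Relative to the median gene this was a log2 ratio of 3.69 (3.52 to 3.87), or 12.9-fold. At least 1 fragment was seen in 72.6% of proximal tubule-like nuclei, and in 2.96% (endothelial-like) to 11.4% (intercalated-like) of nuclei of the other named classes, whose median depth was lower. Between segments, Slc2a2 was at 244.5 CPM in S1-like nuclei (232.0 to 257.4), 206.3 in S2-like (197.2 to 215.6) and 115.2 in S3-like nuclei (104.9 to 126.3). Outside the proximal tubule, named classes lay between 7.54 CPM in mesenchymal-like nuclei (3.90 to 13.2) and 22.8 in intercalated-like nuclei (13.0 to 37.0). Unnamed clusters held 145 of the 277 other fragments. Against the 2314 nuclei of the other named classes alone, the rate of 11.3 CPM (9.41 to 13.3) gave 17.7-fold, in place of 9.29-fold against all other nuclei, both before setting the ratio relative to the median gene.

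**Figure D1:**
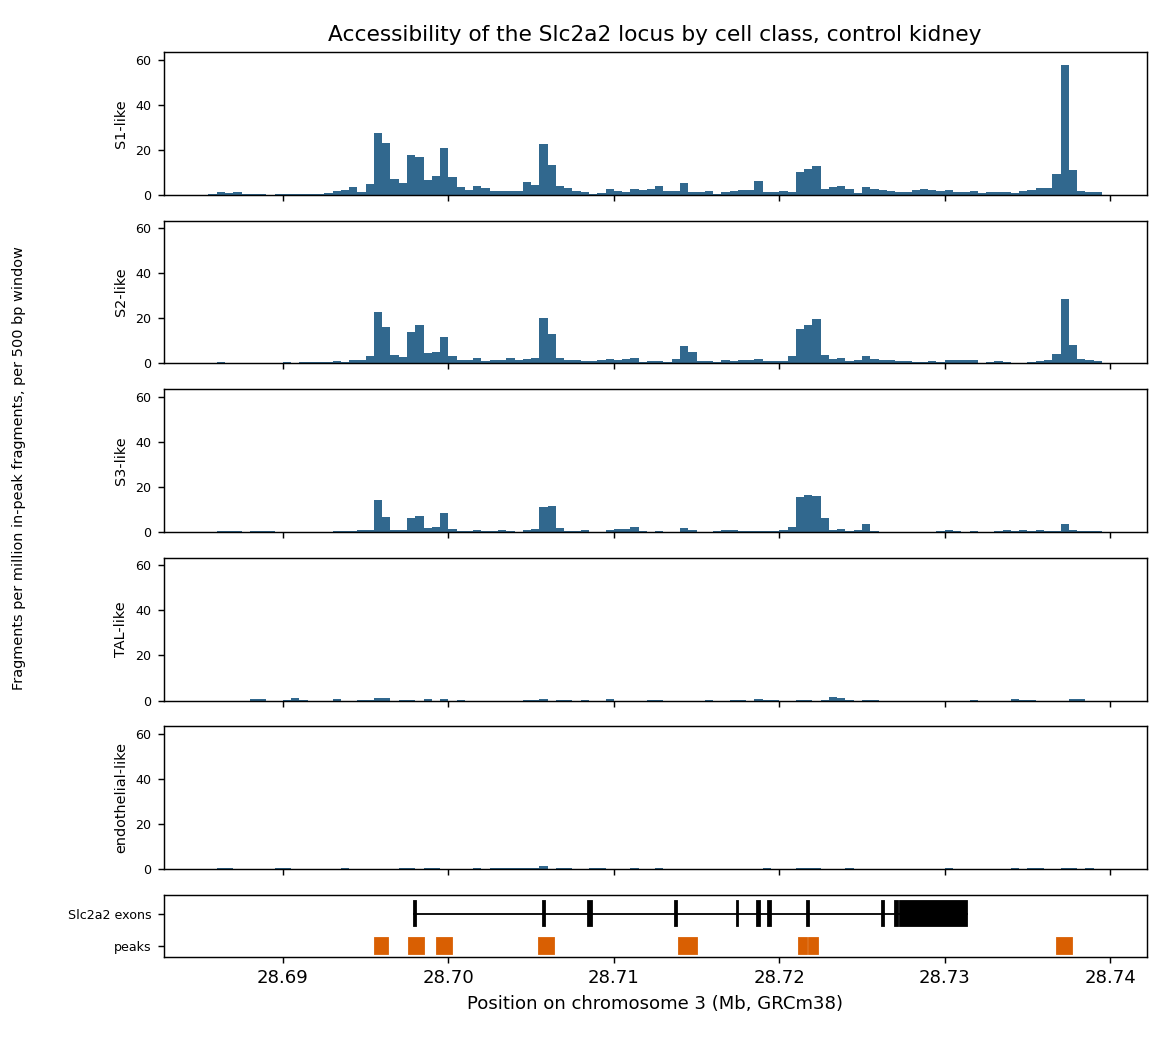
Fragments in 500 bp windows, scaled to in-peak fragments (CPM, y axis), across the Slc2a2 locus (x axis, position on chromosome 3 in Mb, GRCm38), in 5 cell classes of the control kidney, with exons in black and peaks in orange. The downstream peak falls from 61.0 CPM in S1-like to 3.55 in S3-like nuclei, and the same windows are low in TAL-like and endothelial-like nuclei.

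The Slc2a2 locus held 8 peaks, which differed between segments. The peak with the most fragments in proximal tubule-like nuclei lay downstream of the gene, at 28736779 to 28737670, with 34.5 CPM (31.9 to 37.2). It was at 61.0 CPM in S1-like nuclei (54.9 to 67.7), 30.8 in S2-like (27.4 to 34.6) and 3.55 in S3-like nuclei (1.94 to 5.96). A peak upstream of the start site, at 28695560 to 28696330, went from 39.0 CPM in S1-like (34.1 to 44.4) to 15.7 in S3-like nuclei (12.1 to 20.2). The peak over exon 1 at 28697601 to 28698497 went from 27.1 (23.1 to 31.7) to 10.7 (7.68 to 14.4). Peaks in intron 1 and over exon 2 also fell, from 26.8 (22.8 to 31.3) to 8.63 (5.98 to 12.1) and from 27.5 (23.4 to 32.0) to 17.8 CPM (13.9 to 22.4). The peaks in intron 4, in intron 7 and over exon 8 did not follow this order. In intron 7 the values were 12.4 CPM in S1-like (9.70 to 15.6), 17.9 in S2-like (15.3 to 20.8) and 19.3 in S3-like nuclei (15.2 to 24.1), and in intron 4 they were 6.27, 10.8 and 2.03. The peak over exon 8, at 28721785 to 28722348, was at 15.4 CPM in S1-like (12.4 to 18.9), 22.4 in S2-like (19.4 to 25.6) and 17.3 in S3-like nuclei (13.4 to 21.9). The S1-like and S2-like intervals did not overlap, whereas the S3-like interval overlapped both. The segments were formed from the same fragments, and mice could not be compared.

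Some other genes of sugar handling differed between segments of the proximal tubule, and others barely did. Values are log2 ratios of a segment over the other proximal tubule-like nuclei, relative to the median gene. G6pc, the catalytic subunit of glucose-6-phosphatase, followed Slc2a2, at 0.56 in S1-like nuclei (0.42 to 0.70) and -1.28 in S3-like nuclei (-1.54 to -1.05), beside 0.42 (0.32 to 0.51) and -0.80 (-0.95 to -0.66) for Slc2a2. Pck1 and Fbp1, which encode enzymes of gluconeogenesis, varied less, from -0.18 for Pck1 in S3-like to 0.13 for Pck1 in S2-like nuclei. The sodium-glucose cotransporter gene Slc5a1 was lowest where Slc2a2 was highest, at -2.92 in S1-like (-3.24 to -2.63), 1.17 in S2-like (1.02 to 1.32) and 0.55 in S3-like nuclei (0.39 to 0.71). Slc5a8, a monocarboxylate transporter, was at -3.81 in S1-like (-4.16 to -3.49) and 1.07 in S3-like nuclei (0.95 to 1.19). Slc5a10 and Khk, the latter encoding fructokinase, stayed between -0.08 and 0.15 in the 3 segments. Agt, the angiotensin precursor gene, was higher in S3-like nuclei (1.43, 1.25 to 1.61) than in S1-like (-1.33, -1.58 to -1.09). The comparison of a segment with the other proximal tubule-like nuclei was added after the data were examined. Apart from Slc2a2, no rule fixed beforehand chose genes for it. Pck1, Fbp1, Slc5a8 and Agt met the fixed rule for proximal tubule over other nuclei. The other genes were chosen from the fixed lists after their values were seen.

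Gene lists of proximal tubule function were more accessible in proximal tubule-like nuclei than in all other nuclei, as the plot of list medians shows. Values are log2 ratios relative to the median gene of the class, whose own ratio was -0.475 in proximal tubule-like nuclei and between -0.098 and 0.331 in the other named classes. Of 20 lists, 9 lay above the central range of random lists and 2 below it. Glucose and sugar transport had a median of 1.3 over 14 genes, with 12 above the median gene and a percentile of 100, and 2.16 over promoters alone. Its leading members were Slc5a8 (3.85, 3.62 to 4.09), Slc2a2 itself and Slc5a11 (2.52, 2.38 to 2.66), whereas Slc2a1 (-0.96, -1.05 to -0.87) and Slc2a4 (-1.73, -1.91 to -1.55), the glucose transporters Glut1 and Glut4, were lower. Gluconeogenesis had a median of 0.50 over 18 genes (percentile 99.1), with 16 above the median gene. It was led by Pck1 (3.89, 3.69 to 4.10), which encodes phosphoenolpyruvate carboxykinase, and Fbp1 was at 3.0 (2.86 to 3.14). Foxo1 was at -0.01 (-0.08 to 0.05), and Pck2, the mitochondrial counterpart of Pck1, at -0.84 (-1.03 to -0.66). Over promoters alone the gluconeogenesis median was 0.19 (percentile 98.0), still above the range.

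**Figure D2:**
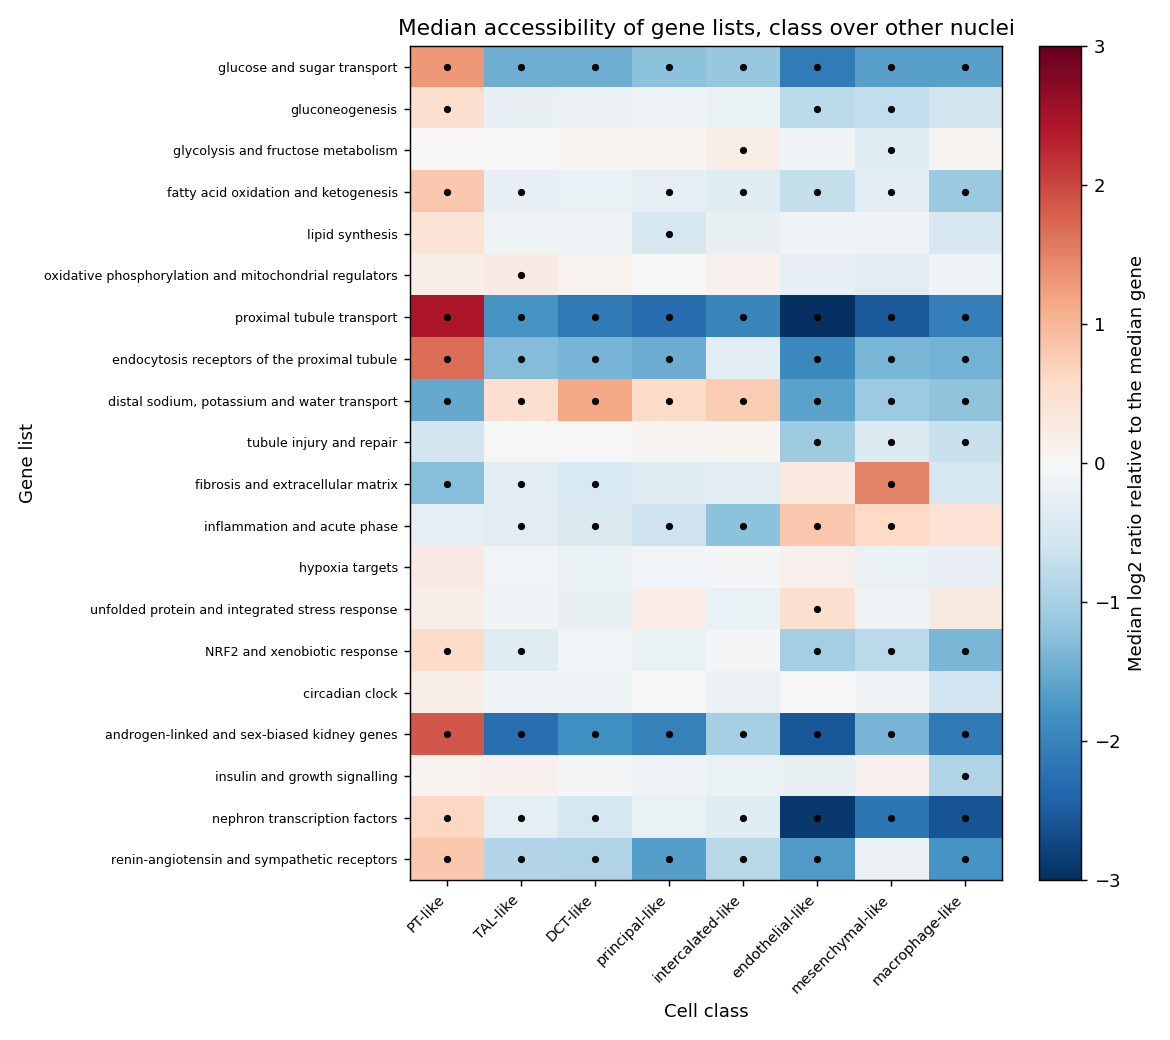
Median log2 ratio of each gene list (y axis) in each cell class over all other nuclei (x axis), relative to the median gene, with colour from blue (-3 or lower) to red (3 or higher). Black dots mark medians outside the central 95% of 10000 matched random lists, and proximal tubule transport in proximal tubule-like nuclei is the highest at 2.42.

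Glycolysis and fructose metabolism did not stand apart as a list, because its members went both ways. Its median was 0.02 over 26 genes, with 13 above and 13 below the median gene and a percentile of 30.8, and it was -0.12 over promoters alone. Pklr, a pyruvate kinase gene, was at 2.66 (2.44 to 2.89), Mlxipl, which encodes the glucose-responsive factor ChREBP, at 2.12 (2.03 to 2.20), and Sord, the sorbitol dehydrogenase gene, at 2.09 (2.0 to 2.18). The hexokinase genes Hk1 (-3.39, -3.51 to -3.27) and Hk3 (-1.72, -2.10 to -1.35) were lower in proximal tubule-like nuclei. Oxidative phosphorylation was at 0.17 (percentile 64.6), with Esrrg at 0.82 (0.78 to 0.85), Ppargc1b at 0.80 (0.75 to 0.85), Ogdh at 0.77 (0.71 to 0.83), Nrf1 at -0.15 (-0.23 to -0.06) and Esrrb at -1.18 (-1.26 to -1.10).

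Fatty acid oxidation and ketogenesis had a median of 0.80 over 27 genes (percentile 100), with 25 above the median gene. The omega-hydroxylase genes Cyp4a31 (2.73, 2.44 to 3.05), Cyp4a14 (2.22, 1.85 to 2.64) and Cyp4a10 (2.01, 1.70 to 2.35) led it, and Hadhb (-0.05, -0.16 to 0.07) and Acaa2 (-0.29, -0.38 to -0.21) were its lowest members. Its median over promoters alone was 0.48. Lipid synthesis had a median of 0.42 (percentile 97.2), inside the central range. Me1 (2.62, 2.51 to 2.73), Dgat2 (1.79, 1.72 to 1.87) and Hmgcs1 (2.19-fold) were higher, and Acacb (-2.30, -2.40 to -2.20) and Scd2 (-2.37, -2.57 to -2.18) were lower. It passed above the range at 0.46 (percentile 97.9) when unnamed nuclei were left out of the reference, but stayed inside it over promoters alone.

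Proximal tubule transport had the highest list median, 2.42 over 20 genes (percentile 100), with 19 above the median gene. Aqp1, the water channel of this segment, was at 3.82 (3.64 to 4.01), Slc47a1 at 3.50 (3.38 to 3.63) and Slc22a12, which encodes the urate transporter Urat1, at 3.20 (3.03 to 3.39). Slc16a1 (0.90, 0.75 to 1.05) and Abcc4 (-0.10, -0.16 to -0.04) were its lowest members. Endocytosis receptors had a median of 1.68 over 10 genes (percentile 100), led by Pdzk1 (3.42, 3.29 to 3.56), Ggt1 (2.23, 2.14 to 2.32) and Amn (2.22, 2.04 to 2.41). The X-linked genes Clcn5 (-0.06, -0.15 to 0.03) and Ocrl (-1.09, -1.32 to -0.86), both mutated in renal tubular disorders, were the lowest of that list. The endocytosis median fell to 0.46 over promoters alone. Without doublet removal it was 1.1 and that of transport 1.45, but there a cluster of 422 nuclei that scored highest for S2 stayed unnamed and sat in the reference.

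Genes linked to androgens or biased between the sexes had a median of 1.87 over 13 genes (percentile 100), with 12 above the median gene. All mice were male, so no comparison between the sexes was possible and an effect of androgens was not tested. Cyp2a4 was at 4.32 (3.90 to 4.79), Odc1 at 0.38 (0.30 to 0.47) and Gsta4 at -0.61 (-0.78 to -0.45). The NRF2 and xenobiotic list had a median of 0.54 (percentile 99.8), with Ugt2b38 at 3.40 (3.07 to 3.76), Cyp2d26 at 3.39 (3.03 to 3.80) and Cyp2j5 at 3.33 (3.16 to 3.51). Slc7a11, the cystine transporter gene, was at -1.43 (-1.53 to -1.33). Nephron transcription factors had a median of 0.61 over 25 genes (percentile 100), with Nr1h4, the bile acid receptor FXR, at 2.54 (2.45 to 2.64), Hnf4g at 2.14 (2.01 to 2.27), Ppara at 1.94 (1.87 to 2.01) and Tfap2b at -3.28 (-3.54 to -3.04). Renin-angiotensin and sympathetic receptors had a median of 0.80 over 15 genes (percentile 100), with 9 above the median gene. Adra2b (2.53, 2.37 to 2.70), Ace (2.36, 2.22 to 2.52) and Agt (2.11, 1.91 to 2.33) led it, and Adra2a (-1.23, -1.58 to -0.90) and Adrb1 (-3.15, -3.48 to -2.85) were lowest. In the proximal tubule (PT) over promoters alone, the renin-angiotensin median was 2.04, and over peaks alone it was 1.97 and the androgen median 2.92. Without doublet removal, and with the same 422 S2-scoring nuclei in the reference, the androgen median was 1.17 and that of transcription factors 0.37.

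Genes of distal transport and of extracellular matrix were less accessible in proximal tubule-like nuclei. Distal sodium, potassium and water transport had a median of -1.54 over 22 genes (percentile 0), with 17 below the median gene, and -0.97 over 16 genes without those that led a cluster. Kcnj1, the potassium channel ROMK, was at -4.23 (-4.51 to -3.97). Kcnj15 (3.42, 3.29 to 3.55), Aqp3 (0.97, 0.79 to 1.15) and Kcnj16 (0.89, 0.81 to 0.98), of the same list, were higher in the proximal tubule. Fibrosis and extracellular matrix had a median of -1.28 over 18 genes (percentile 0), with 15 below the median gene, among them Pdgfrb (-1.96, -2.12 to -1.8) and Thbs1 (-1.90, -2.06 to -1.74). Postn (0.69, 0.32 to 1.08) and Fn1 (0.46, 0.27 to 0.65) were above it. Counted over promoters alone, that list had a median of -0.20 and a percentile of 6.34, which ended the call. Both lists held markers that named nuclei of the reference. For distal transport, the 16 genes left without cluster leaders still included Kcnj1, Klhl3, Wnk4, Hsd11b2 and Aqp3. For matrix, such markers included Pdgfrb and Col1a1. Part of the low medians may therefore follow from the naming of the other classes.

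The injury and inflammation lists lay inside the central range but held members that went strongly both ways. Tubule injury and repair had a median of -0.55 (percentile 3.63), with Krt20 at 2.06 (1.63 to 2.54), Cxcl1 at 1.94 (1.66 to 2.23), Itgb8 at 1.92 (1.82 to 2.02), Anxa2 at -3.90 (-4.13 to -3.69) and Krt7 at -3.95 (-4.26 to -3.68). Inflammation and acute phase had a median of -0.26 (percentile 16.1). Its fibrinogen genes Fga (4.0, 3.53 to 4.56) and Fgg (3.35, 2.91 to 3.85) and the complement gene C3 (1.66, 1.49 to 1.84) were accessible in proximal tubule-like nuclei, and the cytokine gene Csf1 (-1.91, -2.08 to -1.75) was lower. Over promoters alone, the injury list was at -1.09 (percentile 0.43) and the inflammation list at -0.33 (percentile 0.75), both below the range. Over peaks alone they were at 0.14 and 0.06, and the stress response list at -0.09, all inside the range.

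Hypoxia targets had a median of 0.24 (percentile 80.05), with Ndrg1 at 1.41 (1.35 to 1.46), Bnip3 at 1.0 (0.91 to 1.09), Car9 at 0.92 (0.75 to 1.11) and Pdk1 at -0.96 (-1.06 to -0.86). The unfolded protein and integrated stress response was at 0.19 (percentile 84.5), with Chac1 at 0.89 (0.68 to 1.11), Fgf21 at 0.79 (0.37 to 1.23), Gdf15 at 0.70 (0.60 to 0.79), Trib3 at -0.48 (-0.71 to -0.27) and Atf3 at -0.82 (-0.91 to -0.73). Circadian clock genes were at 0.21 (percentile 63.2), with Hlf at 1.81 (1.74 to 1.87), Nfil3 at 0.88 (0.78 to 0.97), Per1 at -0.30 (-0.36 to -0.24) and Cry1 at -0.48 (-0.59 to -0.38). Insulin and growth signalling was at 0.10 (percentile 38.0), with Mtor, the kinase of the mTOR complexes, at 2.23 (2.17 to 2.30), Igfbp1 at 2.14 (1.92 to 2.36), Igfbp4 at 1.98 (1.88 to 2.08) and Igf1 at -1.78 (-1.94 to -1.62). Over its promoter alone, Mtor was at 0.33 (0.19 to 0.48).

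The intercalated, endothelial, mesenchymal, macrophage, principal, TAL and DCT classes had fewer lists above the central range. Distal transport genes were high in DCT-like (median 1.15), intercalated-like (0.77), principal-like (0.57) and TAL-like nuclei (0.51), each at a percentile of 100. Over promoters alone it was at 0.27 in TAL-like nuclei (percentile 98.0), and in intercalated-like nuclei the call ended (0.25, percentile 94.6). Oxidative phosphorylation was high in TAL-like nuclei, at 0.25 with 18 of 20 genes above the median gene (percentile 99.8). It was also above the range in S1-like nuclei (0.31, percentile 98.2), but not in S2-like (0.12, percentile 64.9) or S3-like nuclei (0.04, percentile 45.3). Fibrosis and extracellular matrix was high in mesenchymal-like nuclei, at 1.49 with 13 of 14 genes above the median gene (percentile 100), and at 0.69 over promoters alone. Inflammation and acute phase was high in endothelial-like (0.80, percentile 100) and mesenchymal-like nuclei (0.60, percentile 99.6). The former fell to 0.49 without the minimum of fragments per gene, and the latter to 0.33 over promoters and to 0.27 (percentile 93.2), inside the range, when only peaks were counted. In endothelial-like nuclei the stress response list was at 0.48 (percentile 99.1) but at 0.18 over promoters (percentile 78.1) and 0.33 over peaks (percentile 92.6), inside the range both times. Glycolysis in intercalated-like nuclei, at 0.20 (percentile 97.9), was inside the range over promoters (0.05, percentile 69.8), without doublet removal (0.15, percentile 94.0) and over peaks (0.14, percentile 92.4). No list was above the range in the 99 macrophage-like nuclei. Inflammation passed above it there over promoters alone (0.60, percentile 99.9) and without the minimum of fragments per gene (0.66, percentile 98.4). Lists below the range numbered 11 in macrophage-like, endothelial-like and mesenchymal-like nuclei and 10 in TAL-like nuclei. They numbered 8 in DCT-like and principal-like nuclei and 7 in intercalated-like nuclei. Proximal tubule-like nuclei hold most in-peak fragments of the reference of these classes, so low lists there partly mirror lists high in the proximal tubule.

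**Figure D3:**
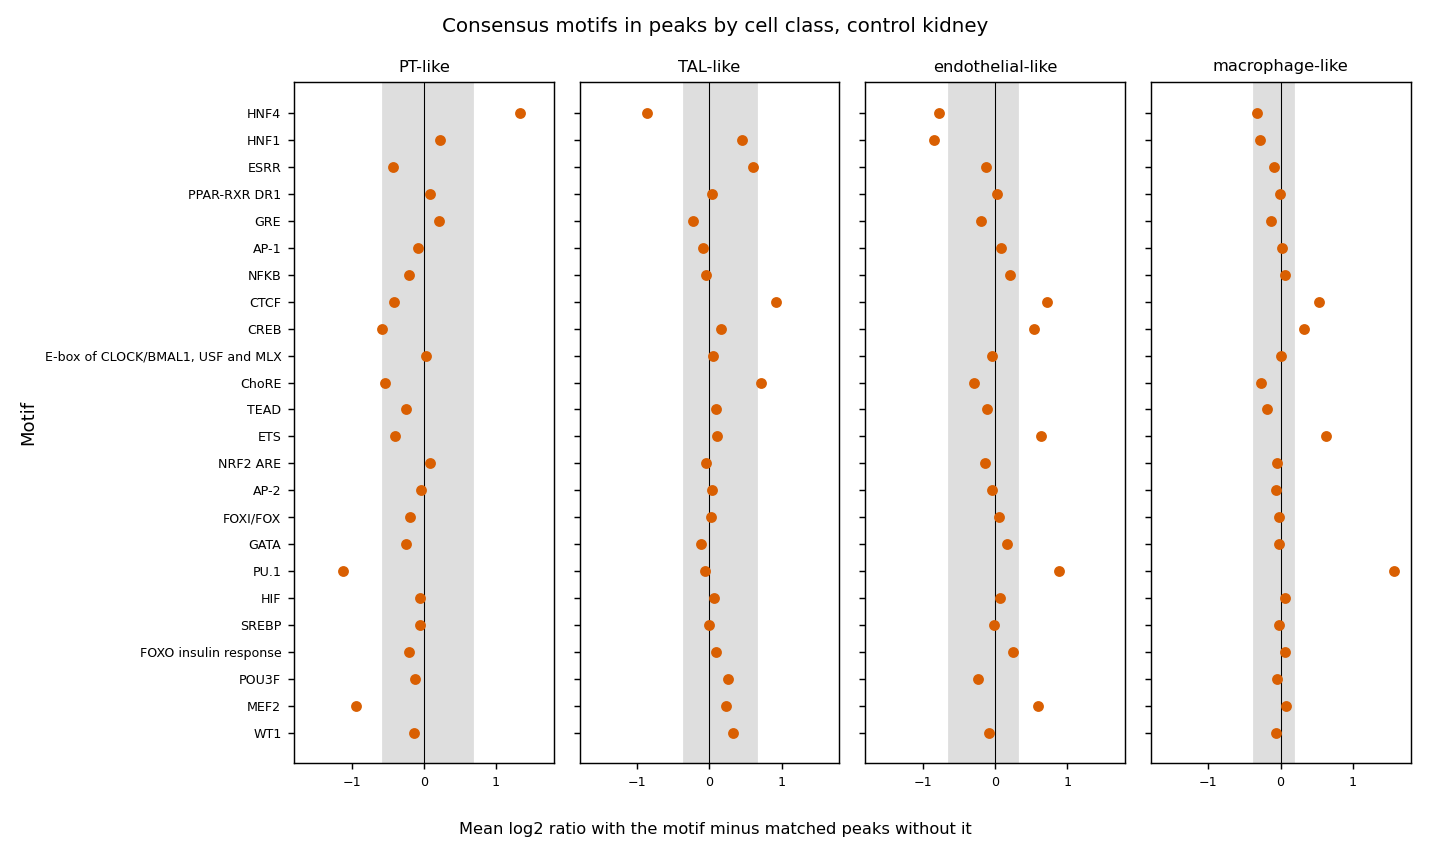
Mean log2 ratio of peaks with a motif minus matched peaks without it (x axis) for each consensus motif (y axis), in 4 cell classes over all other nuclei. Grey bands span the 24 letter-reversed controls, and HNF4 in proximal tubule-like nuclei lies outside its band at 1.33.

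Peaks with the HNF4 motif, bound by a transcription factor family of the proximal tubule, were more accessible there. In 3042 peaks with the motif the mean log2 ratio exceeded that of matched peaks by 1.33, while the 24 reversed controls ranged from -0.57 to 0.68. In the other named classes the values ran from -0.33 in macrophage-like to -0.86 in TAL-like nuclei. Proximal tubule-like nuclei hold most in-peak fragments of the reference there, so values of the other classes partly mirror theirs and are not independent. The HNF1 motif was at -0.84 in endothelial-like nuclei (349 peaks), and at 0.71 in S1-like nuclei, where a control reached 0.76. That control was found in only 10 peaks, and the next highest control in S1-like nuclei was at 0.28 over 85 peaks. The PU.1 motif, of a myeloid transcription factor, was at 1.57 in macrophage-like and -1.13 in proximal tubule-like nuclei, over 94 peaks, the latter -2.0 with only peak centres searched. The ETS motif was at 0.64 in endothelial-like, 0.63 in macrophage-like and 0.55 in mesenchymal-like nuclei, and the MEF2 motif at -0.94 in proximal tubule-like nuclei. CTCF was at -0.42 in proximal tubule-like nuclei over 4758 peaks, inside the range of the controls. The lower limit of that range, -0.57, came from a control found in only 91 peaks. In the other named classes, whose reference holds the proximal tubule-like nuclei, CTCF was between 0.53 in macrophage-like and 0.94 in DCT-like nuclei. The glucocorticoid response element, at 0.22 in proximal tubule-like nuclei, lay inside the range of the controls, and the carbohydrate response element was found in only 13 peaks. A motif match does not show binding, and factors of 1 family share a motif.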

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

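The tests of stray chromatin, of unnamed clusters 12 and 16 and of doublets without cluster 16 were chosen after the Slc2a2 values were seen, and the reading of the stray chromatin test was changed again after its result. The other tests were set down before their results.

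Barcodes that did not pass as nuclei held 32.3% of all fragments, of which 17.6% lay in peaks, and these fragments were left out of all comparisons between cell classes. On unplaced scaffolds, outside the chromosomes analysed, 111890 of 185273 fragments lay in peaks.

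Some Slc2a2 fragments came from nuclei outside the proximal tubule-like class, 277 in all, of which 145 were in unnamed nuclei. Cluster 16 had markers of the proximal tubule at a median of 80.7% of their rate per fragment in proximal tubule-like nuclei. Markers of other classes were not compared in this way. Its highest marker score was for neutrophils, with 0 of those markers passing the naming limits. It had few fragments in peaks (24.8%) and a start site enrichment of 8.3. Proximal tubule nuclei of low quality may account for its 97 fragments. However, its median doublet score (0.425) was the highest of the clusters. Its median of 31833 fragments per nucleus was above the 15070 of all nuclei, so doublets stay possible. In cluster 12, which scored highest for thin limb markers and took that name with some other filters, Slc2a2 reached 35.3% of its proximal tubule rate (25.4 to 47.9), which 2 of 13 other proximal tubule transport genes also reached, Slc6a18 at 44.7% and Slc13a1 at 46.3%, while the rest lay at 12.0 to 34.3%, so proximal tubule chromatin may be a source there but the ranking of Slc2a2 near the top stays open. Nuclei with low doublet scores kept 68.1% of the rate (53.9 to 84.9), a fall that came from cluster 16, which has 0 nuclei with such scores, since without that cluster they kept 102.3% (81.0 to 127.5), so doublets cannot be told apart from other sources in cluster 16. Of the other nuclei's Slc2a2 fragments 35.4% touched a peak (62.0% in proximal tubule-like nuclei), which had been set to exclude stray proximal tubule chromatin as the only source, but that bound was wrong, because Slc2a2 fragments outside nuclei touched peaks at 41.3%, so this source stays open too, and no biological explanation was tested.

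Mtor was 2.23 log2 units above the median gene in proximal tubule-like nuclei. The 200 genes nearest to it in length had a median of -0.11, which argues against gene length. Over the promoter alone the ratio was 0.33 (0.19 to 0.48), so elements away from the promoter may carry most of the difference. Angptl7 lies within the span of Mtor and shares fragments with it. No biological explanation was tested.

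The median gene was at -0.475 in proximal tubule-like nuclei. Scaling without the 5% of peaks with the highest ratio in the proximal tubule left it at -0.42. Those peaks were picked by ratio and not by number of fragments. Whether a few peaks with many fragments lowered the median was therefore not decided by that test. Scaling to all fragments brought it to -0.05, so the larger share of proximal tubule fragments in peaks may account for it. No biological explanation was tested.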

How the results depend on the processing

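Alternatives chosen after the data were examined were clusters made without peaks near list genes, unnamed nuclei left out of the reference, only peaks of the gene window, and leading genes of clusters left out. No list outside the central range moved to the opposite side of it, but medians inside it changed sign in the proximal tubule: glycolysis to -0.12 over promoters, and injury to 0.14, inflammation to 0.06 and stress response to -0.09 over peaks. The count of nuclei was 4457 with a higher minimum of in-peak fragments, 4224 with at least 40% of fragments in peaks and 5723 when set to the labels' estimate. Fragments in peaks fell to 33.4% with the better covered peaks alone. The proximal tubule-like share was 39.8% without doublet removal, where a cluster of 422 nuclei scoring highest for S2 stayed unnamed, 49.5% with that minimum and 49.7% after thinning each nucleus to it. The log2 ratio of Slc2a2, 3.22 before it was set relative to the median gene, was 4.03 over the promoter, 3.64 scaled to all fragments, 3.82 with clusters made without peaks near list genes and 4.14 with unnamed nuclei left out. The HNF4 effect was 1.77 with the central 200 bp searched. The causes were not tested. The other 13 main alternatives stayed within their range, with 9 to 10 lists high in the proximal tubule. Among other class shares, motifs, proximal tubule lists and counts of high lists elsewhere, 282 stayed, 17 moved, 4 passed the central range and 1, the proximal tubule fibrosis list over promoters, fell back inside it. List calls also ended in other classes, with 8 of 12 kept in TAL-like nuclei over peaks and 6 of 9 in intercalated-like nuclei over promoters. The planned comparisons between genotypes and their alternatives were not run, since the knockout was not analysed here. No paired analysis was possible because 1 library was analysed and no test was made.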

Other observations

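Values in this part, other than the peak positions, were chosen after they were seen, and none was tested. Genes of hexokinases and pyruvate kinases differed along the nephron. Hk1, low in proximal tubule-like nuclei, was at 1.84 in TAL-like, 1.53 in DCT-like, 1.32 in principal-like and 1.38 in intercalated-like nuclei, as log2 ratios relative to the median gene. Pkm, the pyruvate kinase gene of most tissues, was at -1.55 in proximal tubule-like nuclei and at 1.02 in TAL-like and 1.34 in DCT-like nuclei, while Pklr was at -2.25 and -1.90 in the latter classes. Hk2 was at 3.0 and Hk3 at 3.92 in macrophage-like nuclei. Esrrb, which encodes an orphan nuclear receptor, was at 2.23 in TAL-like and 1.82 in DCT-like nuclei. There, the 2569 peaks with the ESRR motif were also more accessible, at 0.61 and 0.43. The first value lies inside the range of the TAL-like controls, whose upper limit of 0.66 came from a control found in only 10 peaks. The reversed ESRR motif was at -0.09 in TAL-like nuclei over 1218 peaks. In proximal tubule-like nuclei, which hold most in-peak fragments of the reference, the ESRR motif was at -0.425, inside its control range. The TAL-like and DCT-like values partly mirror that value. Esrrg, by contrast, was more accessible in proximal tubule-like nuclei (0.82), where the motif was lower.

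The other 2 unnamed clusters, 14 and 15, held 62 nuclei (1.35%) and 53 nuclei (1.15%). Markers of T and natural killer cells scored highest in cluster 14, too close to those of B cells, and markers of podocytes in cluster 15, too close to those of mesenchymal cells.

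The 5 peaks with the highest ratio in proximal tubule-like nuclei lay on chromosome 1 at 24211101 to 24212017 (within Col9a1) and 123316628 to 123317512, chromosome 6 at 73465852 to 73466758, chromosome 15 at 87326012 to 87326920 and chromosome 3 at 26604617 to 26605527. They helped to define the class and are given as positions only.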
